A study of Mus musculus with 11 samples.

How the data were processed

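Heart RNA from female mice was sequenced in 11 samples, 5 from a model of polycystic ovary syndrome (PCOS) made by exposure to anti-Müllerian hormone (AMH) before birth, and 6 from controls that received vehicle (phosphate-buffered saline) before birth. Each sample's group and replicate number were taken from its title, and its column in the table from its short description. The labels give every sample the wild-type genotype and name no litter, batch or day. They do not say whether the samples of a group came from separate mice, so p-values measure the spread between these samples, which may in part be technical.

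Per the labels' protocols, total RNA was extracted with a mirVana kit and libraries were made with a TruSeq stranded mRNA kit. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.38, HISAT2 2.2.1, HTSeq 0.13.5, R 3.4.1 and DESeq2 1.18.1 and the genome build mm10; the notes used here do not say which settings were used or which strand was counted. The authors deposited gene-level FPKM (fragments per kilobase of transcript, scaled to the library's total over the listed genes), one value per gene model and sample. These values were used as they stand, with no further scaling. FPKM divides by the library total and by transcript length, so levels are relative within a library and a few strongly changed, abundant transcripts can shift the others.

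The table holds 21878 rows named by RefSeq accession. Symbols and positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 carries: 13175 rows matched by versioned accession, 5903 by accession with another version, and 2800 stayed without a symbol, which gave 87.2% matched. Xist, Amhr2 and the mitochondrially encoded genes were not analysed here. Depth was read from the values themselves. Within a row, FPKM values are whole multiples of what 1 read is worth, and all 15939 rows above 0 in at least 3 samples gave whole reads in every sample, with a largest accepted distance of 0.15 from a whole number. The recovered reads summed to between 11866291 and 14346620 per sample over the listed genes. The recovery was tested on 1500 simulated genes, of which 1500 came out right. A tested row had a median of 374 reads per sample, and a tested row with a mean FPKM under 2 had a median of 80.

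The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1) in rows with a mean FPKM of at least 1 over the 11 samples, which left 10891 rows, 88.2% of them with a symbol. P-values were adjusted by the Benjamini-Hochberg method over these rows. All differences are PCOS minus control on the log2(FPKM + 1) scale, which understates the change of low genes. A looser list took genes with an unadjusted p under 0.05 and a fold of at least 1.5 on that scale. On simulated data with the real samples' means and spreads (10837 genes, 194 of them changed), 80% of genes changed 1.5-fold, 92.3% of those changed 2-fold and 98.4% of those changed 3-fold were called, and 10 of the 185 calls were unchanged genes. The simulated genes varied independently, which real genes do not. With so many changed genes, an adjusted p of 0.05 also corresponds to a larger unadjusted p than in the real data. The share of real changes found may therefore be lower.

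Gene lists for cell types, cardiac tissue, pathways and complexes (36 lists) were fixed before the data were examined; 32 had at least 3 tested members. They were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 32 lists. Camera with an estimated correlation and fry, limma's self-contained test, were alternatives. For each list the median difference was also placed among 10000 random lists matched on gene length (20 bins, from the length implied by the reads) and mean level (3 bins). Random members were drawn independently, while members of a real list vary together, so extreme percentiles can arise without a group effect. The genes named in the text followed a rule also fixed before the data were examined. It takes the 8 higher and the 8 lower genes with the smallest p among those past adjusted p 0.05, leaving out symbols of predicted genes (Gm and a number, names ending in Rik, names with -ps) but not rows without a symbol, and filling up with the next smallest p, given as values only. It adds the 3 tested members with the smallest p of each list past its test, up to 2 called members of any other list, and always Nppa, Nppb, Myh6, Myh7, Col1a1, Col3a1, Esr1 and Amhr2. Some genes that the rule names are not reported here. Other genes named below were chosen after their values were seen and are marked as such.

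Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean FPKM of 5, median-ratio scaling, quantile normalization, the replicate number as a block, sample weights, a robust prior and leaving out each sample in turn. Alternatives added after the data were seen were limma's voom on the recovered reads, and fits without control libraries 2 and 5 and without control libraries 2, 5 and 6. A further 5 lists were also written after the data were seen, for hepatocytes, resident macrophages, blood leukocytes, lysosome and phagocyte genes, and Fc receptors and immune adaptors. Their scores are means of log2(FPKM + 1) over tested members, compared by exact two-sided permutation over the 462 splits of 11 samples into 5 and 6. The scan for genes whose control values part 2 samples from 4 was tested on simulated data with 200 such genes, of which 100% were found with the right 2 samples. The spread of the simulated genes was capped at a low value and their shift was well beyond the gap sought. The test thus checks that the scan runs, not its error rate on real genes. A sample was marked as far from its group where its gap to the nearest other sample exceeded Dixon's critical value at 95%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.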

Results

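Female mice exposed to AMH before birth develop features of PCOS, and hearts of such mice were compared with hearts of vehicle-exposed controls to ask which transcripts differ between them. Poly(A)-selected RNA was sequenced in 5 PCOS and 6 control samples. Recovered reads over the listed genes ranged from 11866291 in control replicate 5 to 14346620 in PCOS replicate 3. Transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were near 0 in all 11 samples, with at most 4 reads of Ddx3y in a sample. Control replicate 6 stood apart from the other libraries: its median Pearson correlation with the other samples, across genes, was 0.962, against 0.987 to 0.993 in the other 10, and it held liver transcripts described at the end.

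Ccl8, Cd68, Lgals3 and other genes known from macrophages were higher in PCOS hearts. Of 10891 tested rows, 15 differed at an adjusted p under 0.05 (limma), all 15 of them higher in PCOS. Ccl8, a chemokine that attracts monocytes, rose from 1.68 ± 0.628 FPKM (SD, n = 6) in controls to 12.3 ± 3.61 FPKM (SD, n = 5) in PCOS, the largest difference among the called genes (log2 difference 2.30, SE 0.20, adjusted p = 8.58e-05). Cd68, a lysosomal glycoprotein of macrophages, rose from 4.78 ± 1.66 FPKM to 17.6 ± 2.22 FPKM (log2 difference 1.73, SE 0.17, adjusted p = 0.000298). Lgals3, which encodes galectin-3, rose from 3.03 ± 0.701 FPKM to 9.87 ± 2.09 FPKM (log2 difference 1.43, SE 0.15, adjusted p = 0.000387). In 14 of the 15 genes every PCOS sample lay above every control sample; in Sh3bgrl3 control replicate 6 overlapped the PCOS samples. Among all tested rows, 49 had all PCOS samples above all controls and 27 all below, where chance gives about 24 of each kind.

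Most of the other named higher genes are known from macrophages or other leukocytes, without a test of that theme over the called genes. Ms4a7 and Ms4a4a, membrane-spanning proteins of the MS4A family found on macrophages, rose by log2 differences of 1.47 (SE 0.11, adjusted p = 3.18e-05) and 1.77 (SE 0.18, adjusted p = 0.000387). Wfdc17, a small secreted protein of activated macrophages, went from 10.1 ± 3.30 to 38.6 ± 9.44 FPKM (log2 difference 1.86, SE 0.20, adjusted p = 0.000535). Lilr4b, a leukocyte immunoglobulin-like receptor, had the smallest adjusted p (1.36e-05), at 2.03 ± 0.404 FPKM in controls and 7.24 ± 0.749 FPKM in PCOS. Lilr4b and its neighbour Lilrb4a (log2 difference 0.94, SE 0.11, adjusted p = 0.000865) are near-identical copies, so how reads were split between them is uncertain. A row known only by its transcript model, XM_006526734.2, was also higher (log2 difference 1.17, SE 0.11, adjusted p = 0.000178). The remaining called genes were Trem2, a lipid-sensing receptor of macrophages, the activating receptor Cd300c2, the inhibitory Fc receptor Fcgr2b, the complement receptor C3ar1, and Uap1l1 and Sh3bgrl3. Their log2 differences ran from 0.51 for Sh3bgrl3 to 1.20 for Trem2. In mm10, Ccl8 lies on chromosome 11 from 82115185 to 82116799, Cd68 on chromosome 11 from 69664213 to 69666170, Wfdc17 on chromosome 11 from 83704056 to 83706269, and Lgals3 on chromosome 14 from 47373860 to 47386167. Ms4a7 spans 11321039 to 11336146 and Ms4a4a 11375488 to 11392915 on chromosome 19, and Lilr4b 51480612 to 51486329 on chromosome 10.

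**Figure D1:**
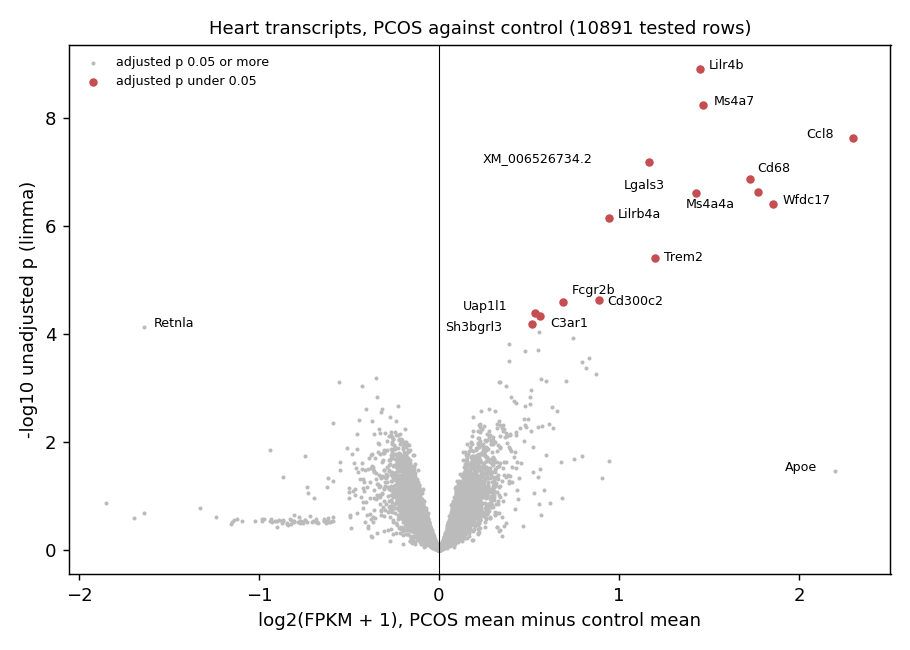
Each point is 1 of the 10891 tested rows, with the difference in log2(FPKM + 1) (PCOS minus control) on the x axis and −log10 of the unadjusted limma p on the y axis. The 15 called genes, in red, all lie on the right; Retnla and Apoe, in grey, did not pass.

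**Figure D2:**
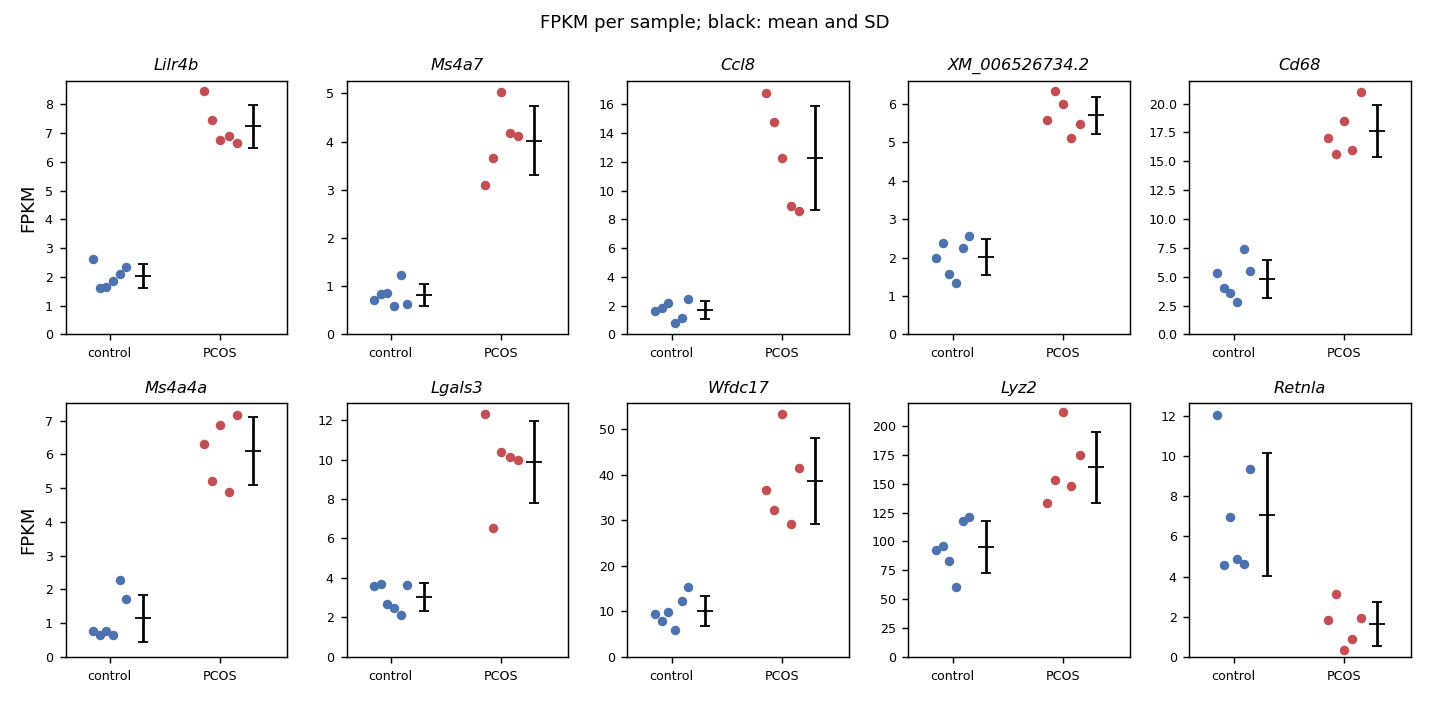
FPKM per sample (dots; 6 control, 5 PCOS) with the mean and SD in black, for the 8 higher named genes and for Lyz2 and Retnla, which did not pass. In each of the 8 named genes the lowest PCOS sample lies above the highest control sample, as for Cd68 at 15.6 against 7.43 FPKM.

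No gene was called lower in PCOS by limma, while 345 rows were lower and 382 higher at an unadjusted p under 0.05, where chance gives 545 in all; voom on the recovered reads also called 0 lower genes. Sample weights called 1, Dnajb12, a chaperone partner (log2 difference −0.40, SE 0.07, adjusted p = 0.0206), and the fit without control replicate 6 called 3 (Dnajb12, Klf9 and Retnla), of which Dnajb12 and Klf9 are named after their values were seen. Retnla, which encodes resistin-like molecule alpha, a product of alternatively activated macrophages, came closest. It was at 7.08 ± 3.06 FPKM (SD, n = 6) in controls and 1.64 ± 1.08 FPKM (SD, n = 5) in PCOS (log2 difference −1.64, SE 0.29, adjusted p = 0.0508), and every PCOS sample lay below every control sample. It passed after median-ratio scaling (adjusted p = 0.0347), after quantile normalization (adjusted p = 0.0337), without control replicate 6 (adjusted p = 0.0482) and without PCOS replicate 2 (adjusted p = 0.0282), and did not in the other 17 alternatives (adjusted p up to 0.191). Further genes by p, given as values only, were the copper-carrying ferroxidase Cp (log2 difference −0.35, SE 0.08, adjusted p = 0.262), Megf9 (−0.56, SE 0.13), Slfn3 (−0.43, SE 0.10), Gpalpp1 (−0.34, SE 0.09), the transcriptional repressor Bcl6 (−0.41, SE 0.11) and Sdhaf3, an assembly factor of succinate dehydrogenase (−0.32, SE 0.09). The looser list held 36 genes, 30 higher and 6 lower, and without control replicate 6 it held 61, 40 higher and 21 lower.

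The number of called genes moved most with 1 control library. When each sample was left out in turn it lay between 10 and 32, with 10 to 15 of the 15 genes among them. Without control replicate 6 it was 32 (29 higher and 3 lower, the 15 among them), and without control libraries 2, 5 and 6 it was 26 (13 of the 15 among them). With a filter at a mean FPKM of 5, which left 7 of the 15 tested, 5 were called, and with sample weights 25. Voom on the recovered reads called 12, all among the 15.

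Of the 32 tested lists, 7 passed camera with the preset correlation, 4 higher and 3 lower. With an estimated correlation none did, all 7 at adjusted p = 0.972, and fry called 0 as well for a shift in 1 direction. The estimated correlation between members ran from 0.25 (insulin signalling) to 0.94 (erythroid markers) in these 7 lists, against the preset 0.01. The p-values with the preset correlation are thus likely too small, and counts of alternatives passed with it too high. Fry's mixed test, for change in either direction, called 1, the macrophage and monocyte markers (adjusted p = 0.0448). Such a test can pass through 1 member, and the list holds Cd68, itself a called gene. The mixed test was not repeated without Cd68. For a shift in 1 direction, fry gave adjusted p = 0.468 for this list. Without control replicate 1, 4 lists passed with the preset correlation. The list of macrophage and monocyte markers had a median log2 difference of 0.53, with 7 of 8 members higher (adjusted p = 1.24e-07 with the preset correlation, adjusted p = 0.972 with an estimated correlation). Of its members 1, Cd68, passed over all genes tested, and 5 passed adjusted over the list alone. Without the filter on low genes, which adds members of the list, the median was 0.205 (adjusted p = 0.00525, the highest of 21 alternatives with the preset correlation). Lyz2, lysozyme of macrophages and monocytes, was at 95.4 ± 22.4 FPKM in controls and 164.1 ± 30.6 FPKM in PCOS (log2 difference 0.79, SE 0.17, adjusted p = 0.152); it passed in 4 of 22 alternatives, among them the removal of control replicate 6 (adjusted p = 0.0349), with a range of 0.0155 to 0.487. C1qc, a chain of complement C1q, was at 26.8 ± 8.41 and 39.9 ± 4.22 FPKM (log2 difference 0.61, SE 0.18, adjusted p = 0.738). Erythroid markers, which report red blood cells left in the tissue, were also higher on average (median 0.71, 6 of 6 members higher, adjusted p = 1.64e-05 with the preset and adjusted p = 0.972 with an estimated correlation). None of these passed over all genes and 6 passed adjusted over the list alone. The erythroid score, the mean over the members, differed by 0.71 log2 and did not pass (exact two-sided permutation p = 0.0649). The named members were Alas2 (log2 difference 0.59, SE 0.22), Hbb-bt (0.80, SE 0.30) and Hba-a1 (0.75, SE 0.29), the last at 274.8 ± 110.1 FPKM in controls and 459 ± 149.6 FPKM in PCOS.

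Nuclear-encoded subunits of the respiratory chain were slightly higher in PCOS on average, with overlap between the groups. The median log2 difference was 0.13 over 64 members, 60 of them higher (camera adjusted p = 4.47e-11 with the preset correlation, adjusted p = 0.972 with an estimated correlation), and 0 members passed over all genes or over the list alone. Ndufa11 went from 153.3 ± 19.6 to 177.4 ± 13.8 FPKM (log2 difference 0.22, SE 0.09, adjusted p = 0.738), and Atp5g1 (log2 difference 0.14, SE 0.06) and Ndufs7 (log2 difference 0.18, SE 0.08) were alike. Control replicate 6 lay among the PCOS samples for Ndufa11, at 189.2 FPKM. PCOS replicate 4, at 154.8 FPKM, lay below control replicate 3, at 162.3 FPKM. The median of the list was 0.192 without control replicate 6 and 0.173 without PCOS replicate 4. Cytosolic ribosomal proteins had a median of 0.08 with 57 of 62 members higher (adjusted p = 0.000432 with the preset correlation, adjusted p = 0.972 with an estimated correlation); 0 passed over all genes or over the list alone. The named members were Rpl21 (log2 difference 0.25, SE 0.14), Rps28 (0.13, SE 0.09) and Rpl18 (0.12, SE 0.08). Across all tested genes the difference fell with gene length (Spearman rho −0.37, across genes, which are not independent replicates), and genes shorter than 1000 bases outside both lists had a median of 0.11. The ribosomal median was 0.166 without control replicate 6, and 0.055 without control replicate 5 or without PCOS replicate 1. Among random lists matched on length and level the respiratory chain median stood at percentile 99.7 and the ribosomal median at percentile 15.7. The ribosomal call was lost under quantile normalization (median 0.033, adjusted p = 0.171), without control replicate 1 (adjusted p = 0.18) and without control libraries 2 and 5 (median 0.012, adjusted p = 0.832), and kept in the other 18 alternatives with the preset correlation (adjusted p down to 2.91e-15). The respiratory chain passed in all 21 of these, but under quantile normalization its median fell to 0.042 (adjusted p = 0.000405, the highest of the 21) and the difference of Atp5g1 to 0.013.

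Targets of PPAR-alpha, the fatty acid-activated nuclear receptor, were lower in PCOS (median log2 difference −0.16, 10 of 12 members lower, adjusted p = 0.00411 with the preset and adjusted p = 0.972 with an estimated correlation). Cpt1a, which brings fatty acids into mitochondria, was at 13.78 ± 1.997 FPKM in controls and 10.99 ± 1.498 FPKM in PCOS (log2 difference −0.30, SE 0.11, adjusted p = 0.738) and Acot2 differed by −0.23 (SE 0.09). Genes of insulin signalling had a median of −0.06, with 16 of 18 members lower (adjusted p = 0.0156 with the preset and adjusted p = 0.972 with an estimated correlation), among them Gsk3b (−0.16, SE 0.07), Pik3cb (−0.17, SE 0.08) and Pdpk1 (−0.23, SE 0.10). The largest difference in that list was Irs2 (−0.69), named after its values were seen. Irs2 was at 7.50 and 8.71 FPKM in control replicates 2 and 5 and at most 2.36 FPKM in the other samples. Genes of cholesterol synthesis and uptake had a median of −0.105, with 12 of 14 lower (adjusted p = 0.0455 with the preset and adjusted p = 0.972 with an estimated correlation). They included Sc5d, at 5.41 ± 1.116 FPKM in controls and 4.567 ± 0.2539 FPKM in PCOS (log2 difference −0.19, SE 0.10, adjusted p = 0.741), and Nsdhl (−0.23, SE 0.13), both enzymes of sterol synthesis. Control replicate 6 was highest in both, at 7.645 FPKM for Sc5d and 4.913 FPKM for Nsdhl, and without it they differed by −0.10 and −0.14. Without that library the cholesterol median was −0.026 and the insulin signalling median −0.14. The cholesterol median was −0.177 without control replicate 2 and −0.067 without PCOS replicate 1, and the PPAR-alpha median −0.243 without PCOS replicate 4. Among random lists matched on length and level the PPAR-alpha median stood at percentile 0 and the cholesterol median at percentile 0.26, while the insulin signalling median stood at percentile 29.5, within what genes of like length and level gave. Some lists that did not pass were as extreme. Smooth muscle and pericyte markers and immediate-early genes stood at percentile 100, and antioxidant genes at 0.16. An extreme percentile therefore does not by itself set a list apart. No member of these 3 lists passed over all genes or over the list alone. With the preset correlation, the PPAR-alpha call was lost in 1 of 21 alternatives, without control libraries 2 and 5 (median −0.073, adjusted p = 0.0706), as was that of insulin signalling (adjusted p = 0.188), which was lost in 3 of 21, also without control replicate 1 (adjusted p = 0.0525) and with the filter at 5 (adjusted p = 0.0611). The cholesterol call was lost in 14 of 21 alternatives, with adjusted p from 4.25e-06 to 0.689. Among these was the removal of control replicate 1, 4 or 6 (adjusted p = 0.0588, 0.0579 and 0.533) or of PCOS replicate 2, 4 or 5 (adjusted p = 0.131, 0.0674 and 0.0824).

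**Figure D3:**
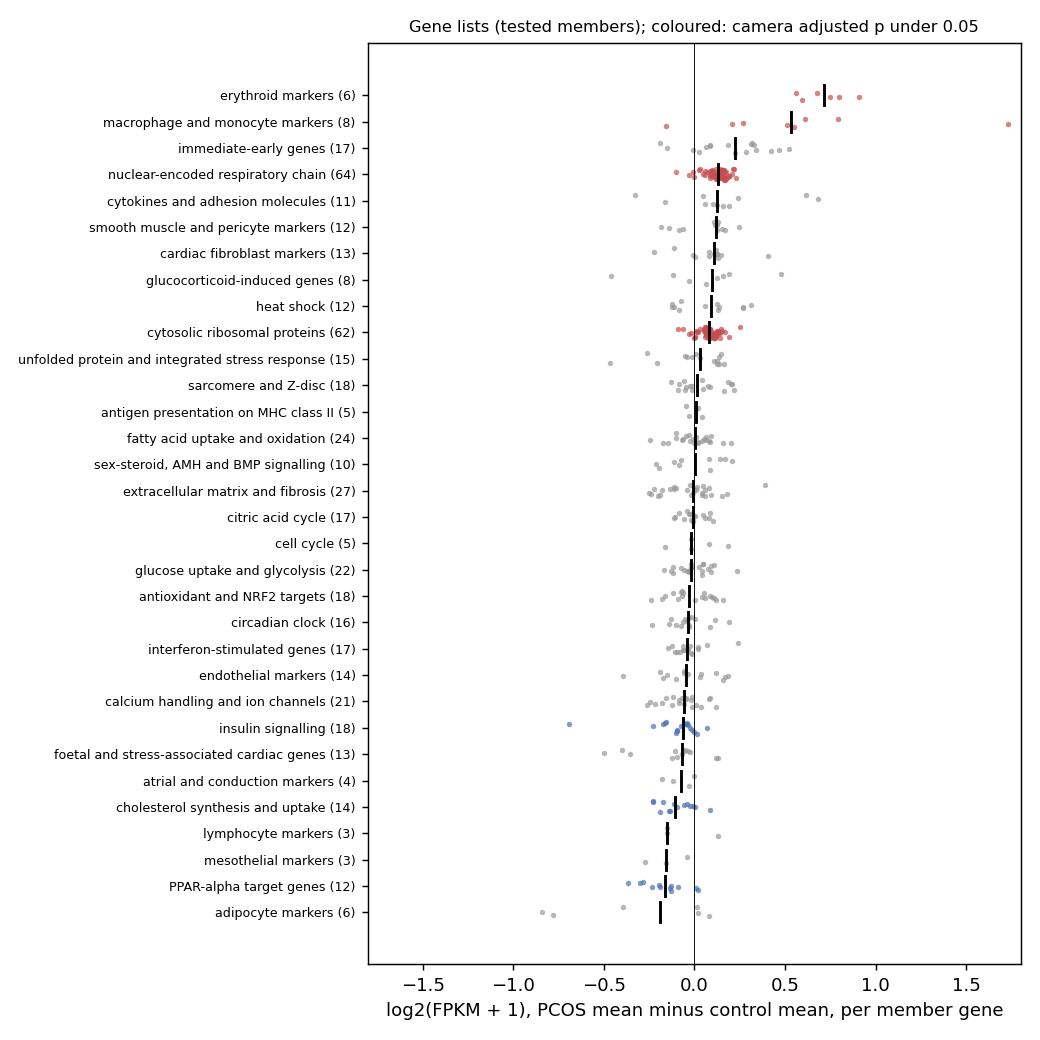
Each point is a tested member of a gene list, at its difference in log2(FPKM + 1) (PCOS minus control), with the list's median as a black bar and the number of members in brackets. The 7 lists past camera with the preset correlation are coloured, 4 higher in red and 3 lower in blue; the sarcomere median, at 0.015, lies near 0.

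Lists of genes of heart muscle and of the extracellular matrix did not pass camera with the preset correlation in the main fit of all 11 samples. The sarcomere and Z-disc list had a median log2 difference of 0.015 over 18 members (adjusted p = 0.264), calcium handling and ion channels −0.055 over 21 members (adjusted p = 0.177) and extracellular matrix and fibrosis −0.007 over 27 members (adjusted p = 0.595). The list of foetal and stress-associated cardiac genes had a median of −0.067 over 13 members (adjusted p = 0.264). It passed as lower in 3 of 21 alternatives, without control replicate 2 (median −0.119, adjusted p = 0.0325), without PCOS replicate 3 (median −0.146, adjusted p = 0.0299) and without control libraries 2 and 5 (median −0.121, adjusted p = 0.00424), with a range up to 0.533. Calcium handling passed as lower in 4 of 21 alternatives (adjusted p from 0.00164 to 0.555). Among these were the fit without control replicate 6 (median −0.124, adjusted p = 0.00378) and sample weights (median −0.116, adjusted p = 0.00662). The lowest value was with the replicate number as a block. Without control replicate 6, camera with an estimated correlation gave adjusted p = 0.524 for calcium handling. Without control replicate 4 the sarcomere list passed as higher (median 0.022, adjusted p = 0.0452, range up to 0.901). Extracellular matrix (median −0.121, adjusted p = 0.00224, range up to 0.99) and endothelial markers (median −0.161, adjusted p = 0.00509, range up to 0.934) then passed as lower. Interferon-stimulated genes did so as well (median −0.134, adjusted p = 0.00606, range up to 0.939). The fit without control replicate 4 was tested with the preset correlation only. Myh6, the main myosin heavy chain of the adult mouse heart, was at 5704 ± 536.8 FPKM in controls and 5651 ± 455.3 in PCOS (log2 difference −0.01, 95% confidence interval −0.18 to 0.16). The natriuretic peptide genes Nppa and Nppb varied widely among samples: Nppa was at 754.6 ± 433.7 and 507.4 ± 89.2 FPKM (log2 difference −0.40, SE 0.31, adjusted p = 0.793) and Nppb at 299.5 ± 180.1 and 271.1 ± 93.9 FPKM (log2 difference −0.02, SE 0.35). Myh7 differed by −0.11 (SE 0.28), and the fibrillar collagens Col1a1 and Col3a1 by −0.13 (SE 0.13) and −0.11 (SE 0.18). Esr1, an oestrogen receptor, was below the level tested, at 0.14 ± 0.103 FPKM in controls and 0.114 ± 0.0643 FPKM in PCOS. Amhr2, the AMH receptor, was not analysed here. Of the other cell types, cardiac fibroblast markers had a median of 0.11 (adjusted p = 0.264), endothelial markers −0.05 (adjusted p = 0.637) and smooth muscle and pericyte markers 0.12 (adjusted p = 0.462). The fibroblast list passed in 2 of 21 alternatives, at the lowest without control libraries 2, 5 and 6 (adjusted p = 0.0149, range up to 0.795). In 7 of the 32 lists the median, the mean and the test differed in sign, none of them past its test.

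Control libraries differed among themselves in ways the labels do not name, in genes chosen after their values were seen. Alb, which encodes serum albumin, was at 852 FPKM in control replicate 6 and at most 1.06 FPKM in the other 10 samples, and Apoa1 at 274 FPKM against at most 2.5. Apoe, which encodes apolipoprotein E, was at 6.04 FPKM in control replicate 2 and 8.29 in control replicate 5, at 180, 158, 98.8 and 486 FPKM in control replicates 1, 3, 4 and 6, and between 274 and 337 FPKM in the PCOS samples. With that spread, Apoe did not pass between the groups (log2 difference 2.202, SE 0.93, adjusted p = 0.738). Without control libraries 2 and 5, 10 genes were called, and all 10 were among the 15.

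**Figure D4:**
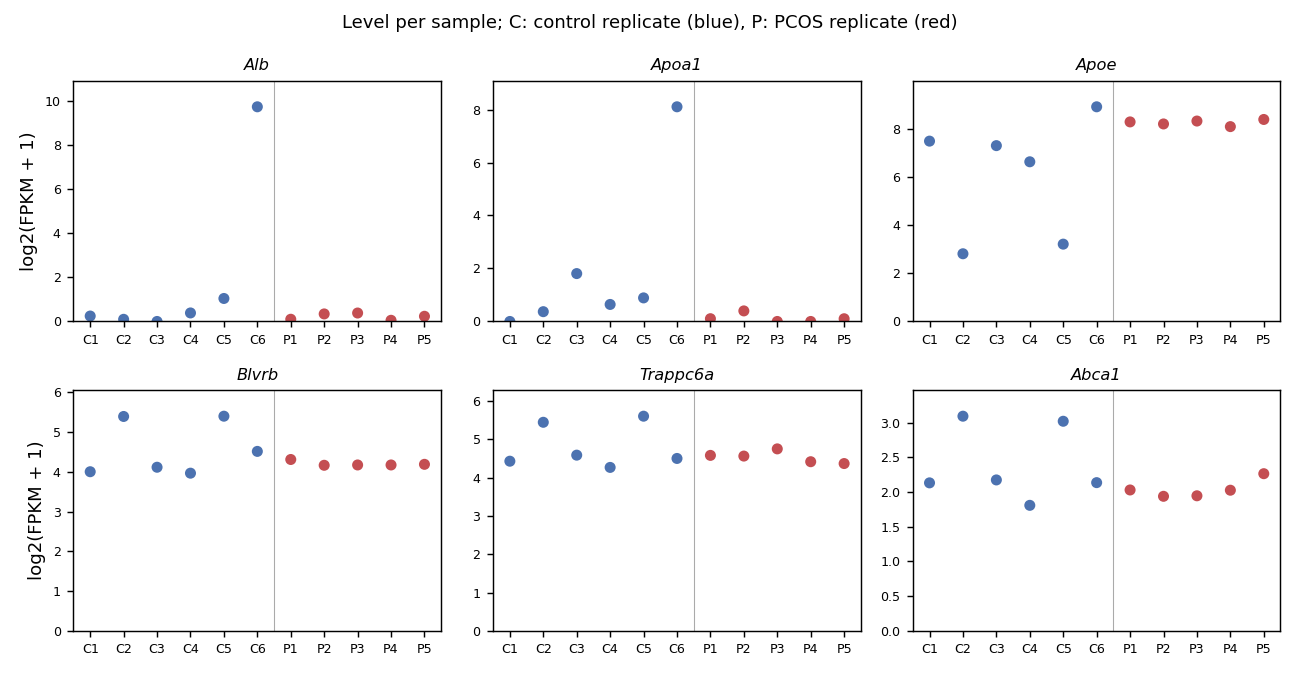
Level as log2(FPKM + 1) of 6 genes in each sample, controls (C1 to C6) in blue and PCOS samples (P1 to P5) in red. Alb and Apoa1 are high in control replicate 6, and Apoe is low while Blvrb, Trappc6a and Abca1 are high in control replicates 2 and 5.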

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

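The tests of other splits of the samples and of residual blood were set before their results were seen; the other tests in this part, and the alternatives that leave out more than 1 control library, were chosen after the result was seen. In 100 of the 462 splits of the samples into 5 and 6, the real one included, 3 gave 15 or more genes past adjusted p 0.05. Few splits thus called as many genes, but with 100 drawn that share is uncertain. The count alone does not tie the calls to the grouping into PCOS and control, since other splits called far more. The highest other split called 931 genes and the next 247. Counts so far above the real one point to a structure of the samples. Both splits put control replicate 6 with at least 3 PCOS samples, but 14 of the 16 drawn splits that did so called 0 genes, so that library alone does not give the structure. The 931 genes came from control replicate 6 with PCOS replicates 1, 2, 3 and 5. These 5 had the highest summed FPKM, 511010 to 556354, against at most 507734 in the others. Summed FPKM may thus be part of the structure, and it partly follows the groups. Control replicates 3 and 6 with PCOS replicates 1, 2 and 5 called 0 genes, though their sums were also high. For the looser list, 13 of 100 splits gave 36 genes or more (the highest other 70), and for gene lists 81 of 100 gave 7 or more (the highest other 17), so chance was not excluded for either count.

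Of 108 groups of values examined, 6 had a sample far from the rest, about what chance gives at 1 in 20, but all 6 were control replicate 6. Its gap to the nearest control sample, as a share of the whole range of the controls, was 0.9562 for the hepatocyte score. It was 0.7672 for Sc5d (7.64 against 5.35 FPKM), 0.6814 for Esr1 (0.341 against 0.13 FPKM), 0.6327 for Rpl18 (280 against 230 FPKM) and 0.6251 for the ribosomal protein score. In these it was the highest control. For Myh6 it was the lowest (4690 against 5580 FPKM), with a share of 0.6351. The 6 flags are not independent: the hepatocyte list was written after the data were seen, and the ribosomal score includes Rpl18.

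The 15 called genes, many of them known from macrophages, were higher in PCOS hearts. Residual blood does not account for them alone: with the erythroid score of each sample as a covariate, the median log2 difference of the 15 called genes went from 1.20 (range 0.51 to 2.30) to 1.08 (range 0.37 to 1.95), and 9 of them kept an adjusted p under 0.05, while the median of the 6 others went from 0.62 (median SE 0.101) to 0.55 (median SE 0.122), with adjusted p from 0.116 to 0.723. These 6 were the receptor genes Trem2, Cd300c2, Fcgr2b and C3ar1, with Uap1l1 and Sh3bgrl3. All 6 stayed higher in PCOS but were no longer called. A lower share of cardiomyocytes would raise other cell types alike. The macrophage score rose by 0.53 log2 more than the mean score of endothelial, fibroblast and smooth muscle lists (exact two-sided permutation p = 0.00866). The macrophage score includes Cd68, itself a called gene, and this comparison was not repeated without it. More macrophages of unchanged make-up would raise all their markers alike, yet the SD of the group differences over the 8 markers, after removing each sample's mean, was 0.61 log2 (exact one-sided permutation p = 0.00216, the smallest the splits can give) and 0.33 log2 over the 7 markers without Cd68 (the same p), with Cd68 at 1.92 and Cd14 at −0.21 on the log2(FPKM + 0.1) scale. A changed macrophage state in PCOS hearts, with or without more cells, may be a hypothesis, found and tested on the same data; markers also expressed by other cells, and shared litter, housing or dissection, which the labels do not give, stay open.

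Liver transcripts appeared in control replicate 6. All 21 of 21 hepatocyte markers were at least 5 times the second highest sample, by a median of 245 times, and together they made up 0.45% of its summed FPKM against at most 0.00303% elsewhere; the most abundant were Alb (852 FPKM), Apoa1 (274 FPKM) and Apoa2 (244 FPKM), and 5 of the 21 (Alb, Apoa1, Apoa2, Ttr and Ahsg) exceeded 1 FPKM in at least 1 other sample. A swapped organ would lack sarcomere transcripts, but their median log2 ratio to the other control samples was −0.10 (SD 0.35 over 18 genes). Reads from liver tissue or RNA, carried over at dissection or during library preparation, may therefore be a source. No biological explanation was tested.

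Apoe was low in control replicates 2 and 5. Counting noise was excluded: with 133 and 156 reads of Apoe, the upper 95% Poisson limit was at most 9.81% of the reads expected at the lowest level of the other libraries. Genes whose 6 control values parted 2 samples from 4 by at least 0.5 log2 made up 5.5% of the 145 tested genes within 10 Mb of Apoe on chromosome 7 and 0.66% of the others (Fisher's exact test, two-sided, p = 9.5e-06; neighbouring genes are not independent), and 6 of the 8 near Apoe parted the same 2 libraries as Apoe. Blvrb, for example, was at 40.9 and 41.1 FPKM in control replicates 2 and 5 and between 14.6 and 21.8 in the other 9 samples, and Trappc6a at 42.7 and 47.8 against 18.3 to 26. These values are consistent with a strain or genotype variant around Apoe in 2 libraries that the labels call wild type, which was found and tested on the same data.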

How the results depend on the processing

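The tests on recovered reads and without several control libraries were chosen after the data were seen. The 8 higher named genes kept an adjusted p under 0.05 in all 172 alternative values in which they were tested, and no alternative fit gave a called gene or list the other sign. Of the 15 called genes, between 5 (filter at a mean FPKM of 5, where fewer genes were tested) and 15 were called in each alternative. The count of 15 became 5 with that filter, 25 with sample weights, 26 without control libraries 2, 5 and 6, and between 10 and 32 when each sample was left out, the highest without control replicate 6. The looser count of 36 became 75 with a pseudocount of 0.1, 19 with the filter at 5, 77 with voom on recovered reads, 87 without control libraries 2, 5 and 6, and between 25 and 61 when each sample was left out. The 7 lists became 0 with an estimated correlation, 0 with fry, 13 without control libraries 2, 5 and 6, and between 4 (without control replicate 1) and 10 when each sample was left out. Of the values of the 7 lists under these alternatives, 126 stayed past adjusted p 0.05 and 35 did not, all with the same direction. The cause was not tested except where fewer genes or samples entered.

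With the replicate number as a block, 25 genes (2 of them lower, Dnajb12 and Nt5c1a) and 65 genes of the looser list were called, and 10 lists. The values gave no sign that the numbers pair the samples. Deviations of same-numbered samples correlated at 0.133, −0.032, −0.118, 0.254 and 0.101, and 0 of 5 PCOS samples correlated best with their own number. With so few samples a pairing is not excluded. Control replicate 6 has no partner, so the block takes it out of the comparison.

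Genes that were not called changed sign where their difference was near 0. Nppb became 0.2312 with the block, 0.2702 with sample weights and 0.0456 without control libraries 2, 5 and 6, and ran from −0.2344 to 0.2312 when each sample was left out. Myh7 became 0.0003 with the block and 0.0336 with sample weights, and ran from −0.2686 to 0.0554. Myh6 ran from −0.0671 to 0.0408, and became 0.0296 without control libraries 2 and 5. Col3a1 became 0.007 without control libraries 2 and 5 and 0.1474 without control libraries 2, 5 and 6. Depth limits the low genes: rows with a mean FPKM under 2 rest on a median of 80 reads per sample.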

Other observations

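The fit without control replicate 6 and its gene lists were planned; the other lists and tests in this part, and the genes named, were chosen after the data were seen. Without that library, 17 further genes passed adjusted p 0.05 (limma, 5 control and 5 PCOS samples), 14 higher and 3 lower in PCOS. The higher ones included Tyrobp, the signalling adaptor of Trem2, at 13.2 ± 2.23 FPKM (SD, n = 5) in controls and 24.1 ± 4.33 FPKM (SD, n = 5) in PCOS (log2 difference 0.82, SE 0.13, adjusted p = 0.0167), and Fcer1g, the shared signalling chain of Fc receptors (log2 difference 0.75, SE 0.13, adjusted p = 0.0328). They also included lysosomal proteases and their partners: Ctss (0.98, SE 0.18, adjusted p = 0.0349), Ctsz (0.49, SE 0.09, adjusted p = 0.0349), Cstb (0.43, SE 0.07, adjusted p = 0.0119) and the thiol reductase Ifi30 (0.61, SE 0.09, adjusted p = 0.012). Cyba, a subunit of the phagocyte NADPH oxidase, was higher by 0.40 (SE 0.06, adjusted p = 0.0167). The lower ones were Retnla, the chaperone partner Dnajb12 (−0.42, SE 0.06, adjusted p = 0.0119) and Klf9, a transcription factor induced by glucocorticoids (31.7 ± 4.54 against 20.2 ± 3.14 FPKM, log2 difference −0.63, SE 0.11, adjusted p = 0.0373). Calcium handling and ion channels (median −0.12, adjusted p = 0.00378) and immediate-early genes (median 0.30, adjusted p = 0.0317) then also passed camera with the preset correlation; with an estimated correlation they were at adjusted p = 0.524 and adjusted p = 0.958. Over all 21 alternatives with the preset correlation, immediate-early genes passed in 7 (adjusted p from 1.32e-10 to 0.814), among them the removal of control replicate 5 (adjusted p = 3.76e-05) and of PCOS replicates 1 and 4 (adjusted p = 0.0228 and 0.0126).

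A pair of groups written from what was seen moved with the called genes over all 11 samples. Fc receptor and immune adaptor genes were higher in 12 of 12 tested members (score difference 0.77 log2, exact permutation p = 0.00216, adjusted p = 0.00648), but 6 of them were called with all 11 samples and 9 with or without control replicate 6, so this list is not independent. Over the 3 other members the difference was 0.46 log2 (exact permutation p = 0.00433). Lysosome and phagocyte genes, which include Ctss, Ctsz, Cstb and Ifi30 named above and so are not independent either, had 15 of 20 members higher and a score of 5.41 ± 0.07 (SD, n = 6) in controls and 5.59 ± 0.08 (SD, n = 5) in PCOS, a difference of 0.18 log2 (exact permutation p = 0.00433, adjusted p = 0.00649 over 3 lists). Without those 4 genes, 11 of 16 members were higher and the difference was 0.09 log2 (exact permutation p = 0.0238). Some of these genes were abundant and alike in both groups, such as Ctsd at 655 ± 26.6 FPKM in controls and 656 ± 60.0 FPKM in PCOS. Whole-heart RNA does not tell which cells express them. That these genes go along with the called ones may be a hypothesis only, from a list written after the data were seen.

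Markers of resident cardiac macrophages gave no clear answer. Their score differed by 0.14 log2 (exact permutation p = 0.385, adjusted p = 0.385), with 7 of 8 members higher, among them Folr2 at 5.31 ± 1.89 FPKM in controls and 6.35 ± 1.16 FPKM in PCOS. Lyve1 was the lower member, at 5.49 ± 2.39 FPKM in controls and 3.82 ± 1.598 FPKM in PCOS. Timd4, the other marker on the list, was below the level tested and also lower, at 0.848 ± 0.289 FPKM in controls and 0.529 ± 0.154 FPKM in PCOS. More macrophages without a change of type could raise this score, and the spread between samples leaves open whether it rose. Of the 8 blood leukocyte markers 2 were tested: S100a8 and S100a9 were at 2.87 ± 2.36 and 4.38 ± 2.49 FPKM in controls and 2.18 ± 0.838 and 3.41 ± 1.53 FPKM in PCOS, and the monocyte receptor Ccr2 was at 0.669 ± 0.224 and 0.539 ± 0.14 FPKM.

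In control replicates 2 and 5, where Apoe was low, 3 targets of the sterol-sensing liver X receptors were higher than in the other 9 samples. Abca1 was at 7.52 and 7.10 FPKM against 2.50 to 3.80, Abcg1 at 3.38 and 3.47 against 0.598 to 2.02, and Mylip at 14.9 and 16.9 against 5.73 to 10.5. Irs2, the insulin receptor substrate, was at 7.50 and 8.71 FPKM there against 0.737 to 2.36. The immediate-early gene Egr1 was at 22 and 20.7 FPKM in control replicates 1 and 4 and between 62.9 and 152 FPKM in the other 9 samples.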
